A study of Homo sapiens with 12 samples.

How the data were processed

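Libraries of polyadenylated RNA from TC71 Ewing sarcoma cells, grown in DMEM with 10% fetal bovine serum, were prepared with a stranded mRNA kit after column purification of RNA, per the labels' protocols. The labels name 4 groups of 3 libraries: wild-type, ID2 knockout clone 1, ID2 knockout clone 2 and a rescue line of clone 2. Each library was assigned to its group by its title. The deposited values were raw read counts per gene, 1 column per library, with Ensembl gene identifiers. Reads were checked with FastQC and aligned with STAR to hg38, per the submitters' processing notes, which give no versions. The read counter, its strand setting, the gene annotation and the filter behind the 21569 genes of the table are not given in the sources used here. Antisense and overlapping genes, and genes with near-identical copies such as the MBD3L, MAGEA, CSAG, HLA, histone, protocadherin and ZDHHC11 families, are therefore uncertain.

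Gene symbols came from a table of gene names for 20717 identifiers. GENCODE release 29 held 20825 of the identifiers and gave hg38 coordinates and gene types, with 14453 protein coding. The other 744 were in neither source, and 2814 identifiers, these included, had no gene symbol. Totals ran from 19420408 to 29748084 counts per library. At this depth 1 count is well under 1 CPM, and a group with no read was given a floor of 3 counts over the group, so that its fold is a lower bound. With 1 to 3 reads in a group the ratio is given with an exact 95% interval. These floors and intervals cover counting error only. Pairs of libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom between 1.59 and 3.41, so none was counted as a repeat of another. The replicate numbers of the titles were checked for pairing by the correlation of deviations from the group means. Between clone 1 and clone 2 the 3 same-numbered pairs had r of 0.121, 0.194 and 0.182 and the other pairs -0.157 to -0.027. Deviations cancel out over a group, so positive values for some pairs force negative ones for others. The numbers may thus pair these groups, but this is weak ground, and the labels name no shared day or batch. Pairing was left out of the main test and allowed for in a simulation and a replicate block. In no other pair of groups were all 3 same-numbered correlations over 0.1.

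The design, the tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM scaling, genes kept by expression per group (minimum count 10), 1 mean per group and all 12 libraries in 1 fit with 8 residual degrees of freedom. This left 17084 genes, which held at least 99.9% of the counts of each library, and the common biological coefficient of variation was 2.95%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 5 comparisons were each clone against wild-type, rescue against clone 2, rescue against wild-type and clone 2 against clone 1. Counts were also made of genes called alike in both clones, of those that moved back in the rescue libraries, and of the share of clone 1 calls with the opposite sign there.

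Of 37 gene lists, those with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with a correlation estimated per list, with Benjamini-Hochberg adjustment over the lists of a comparison. Named genes were ID2, the 12 that rose and 12 that fell in both clones by the smaller of both fold changes, the 10 and 10 that moved back, the 5 that rose and 5 that fell most in each comparison, and up to 4 called members of each list. Outside the lists they needed a mean of 1 CPM or more, no overlap between the groups compared, and a symbol that is not a clone, antisense, pseudogene or similar name. The result of 1 list member that this rule names is not reported here.

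The whole procedure was tested on simulated counts in which 50 genes were changed at each of 4 fold sizes. In clone 1 against wild-type it recovered 40% of those changed 1.25-fold, 74% at 1.5-fold, 88% at 2-fold and 96% at 4-fold, among 16663 genes. In the other 4 comparisons it recovered 54% to 62% of those changed 1.25-fold. Unchanged genes made up 6 of 155 calls there, 17 of 171 for clone 2, 16 of 165 for rescue against clone 2, 11 of 172 for rescue against wild-type and 7 of 163 between the clones, which is above the nominal share in 3 of the 5. Camera with the preset correlation called 1 to 3 lists per comparison although no list had been changed.

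Unchanged groups were simulated 20 times to show what shared libraries give by chance, and 20 times more with the same-numbered libraries of the clones correlated at their mean r of 0.166. The alternatives were DESeq2 size factors or upper quartile scaling in edgeR, no filter, a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, only the groups compared, a replicate block, each library left out in turn, a log2 fold change of at least 1, and camera with an estimated correlation. An alternative without chromosomes 11, 13 and 18 was added after seeing the data; it adjusted p-values again without refitting. Scaling, test, leave-out and block alternatives kept the same 17084 genes.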

Results

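Polyadenylated RNA was measured in 12 libraries of TC71, a human Ewing sarcoma cell line, in 4 groups of 3 libraries. The groups were wild-type TC71, knockout clone 1 and knockout clone 2 of ID2, and a rescue line made from clone 2. ID2 is a helix-loop-helix protein without a DNA-binding domain that binds E proteins and keeps them from DNA. The deposited table held gene counts that summed to between 19420408 and 29748084 per library, and 17084 of its 21569 genes were tested. All means are CPM (counts scaled to a common library total) after TMM scaling, with the SD over n = 3 libraries, and log2 fold changes are from the edgeR quasi-likelihood fit, with SE where given. Folds of groups with 1 to 3 reads are ratios of scaled counts, and those of groups with no read are lower bounds. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Both clones were compared with wild-type to ask what the loss of ID2 changes, and the rescue line with clone 2 to ask what the return of ID2 changes back.

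The targeted gene was examined first. ID2 (ENSG00000115738, hg38 chromosome 2, 8678845 to 8684453, plus strand) stood at 77.9 ± 0.657 CPM (SD, n = 3) in wild-type, 18.1 ± 0.777 in clone 1, 50.9 ± 3.16 in clone 2 and 41.5 ± 0.537 in the rescue libraries. Its RNA fell by 2.11 (SE 0.051) on the log2 scale in clone 1 and by 0.62 (SE 0.044) in clone 2. In the libraries labelled rescue it was not higher than in clone 2 but lower, by a log2 fold change of -0.29 (SE 0.047; edgeR, Benjamini-Hochberg adjusted p = 3.52e-06). The values of the rescue libraries therefore go against their label at the RNA level, and every direction below that rests on it is given for the libraries labelled rescue. A count of RNA does not show whether a frameshifted transcript makes protein, so the counts do not test the knockout itself.

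**Figure D1:**
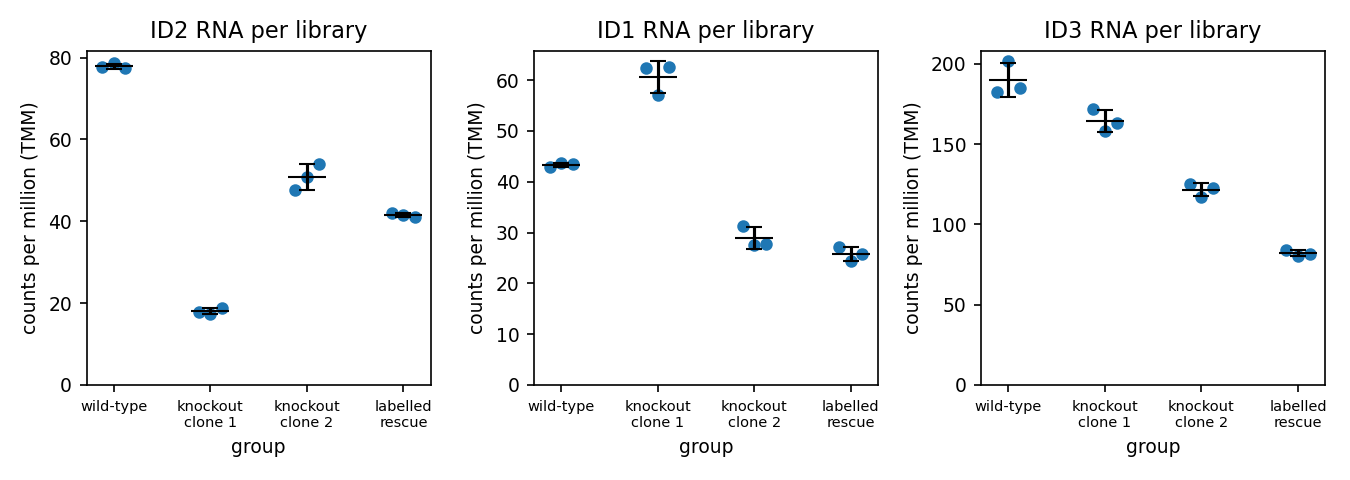
CPM after TMM scaling of ID2, ID1 and ID3 in each of the 12 libraries, by group. Points are libraries, horizontal marks are means and bars are SD (n = 3). ID2 stands at 77.9 CPM in wild-type and at 18.1, 50.9 and 41.5 in clone 1, clone 2 and the libraries labelled rescue.

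The other ID proteins did not move together. ID1 rose in clone 1, from 43.3 to 60.7 CPM, and fell in clone 2, to 28.9 CPM. ID3 fell in both clones, from 189.7 CPM to 164.2 in clone 1 and 121.6 in clone 2, and further to 82.0 in the libraries labelled rescue. ID4 rose in both clones, from 38.3 to 55.1 and 54.0 CPM. Of the E proteins they bind, TCF12 fell in both clones, with log2 fold changes of -0.34 (SE 0.032) and -0.30 (SE 0.032), and TCF3 fell by smaller amounts, while TCF4 rose in clone 1, by a log2 fold change of 0.12 (SE 0.035), and stood at 183.4 CPM in clone 2 against 181.9 in wild-type.

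Clone 1 gained RNA of a keratin and of several genes with few or no reads in wild-type. KRT8, a keratin of simple epithelia, rose from 7.59 to 504.4 CPM, a log2 fold change of 6.07 (SE 0.056). ARAP3, a GTPase-activating protein, rose from 0.272 ± 0.12 to 49.0 ± 1.54 CPM. PNMA5 stood at 18.7 ± 0.553 CPM against 1 read in the 3 wild-type libraries, a ratio of 1390 with a 95% counting interval of 249 to 54930. ANXA3 and CAVIN3 had no wild-type read and were at least 168-fold and at least 116-fold higher, and LAD1 had 1 wild-type read. In the other direction, RET, a receptor tyrosine kinase, went from 3.74 ± 0.0438 CPM to 1 read in 3 libraries, and the amino acid transporter SLC7A2 from 8.10 ± 1.15 CPM to 3 reads. STXBP6 fell to 0.00944 of its wild-type level, NUP210 kept 2 reads, and GPR27, at 0.528 CPM in wild-type, was at least 12.7-fold lower.

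Several gene groups fixed beforehand moved in clone 1. Of 23 cholesterol synthesis genes 20 fell and 0 rose (camera, Benjamini-Hochberg adjusted p = 1.55e-16). Among them HMGCS1, an enzyme of the mevalonate pathway, fell from 241.1 to 86.2 CPM. Of 42 S phase genes 38 fell (camera adjusted p = 3.42e-12), among them the nucleotide synthesis genes TYMS, from 84.0 to 40.8 CPM, and RRM2, from 469.8 to 246.3 CPM. Of 36 collagen and extracellular matrix genes 24 rose and 9 fell (camera adjusted p = 4.56e-15), with COL6A3 at 30.5 CPM against 2.75 and COL9A3 at 56.9 against 7.18. Of 13 epithelial cell markers 8 rose, KRT8, EPCAM, CLDN3 and CLDN4 most, and 1 fell (camera adjusted p = 1.79e-09). Of 37 interferon-stimulated genes 28 rose (camera adjusted p = 5.24e-09), among them BST2, from 0.137 to 5.78 CPM, while HERC5 fell from 8.84 to 0.564 CPM. Of 15 antigen presentation genes 13 rose (camera adjusted p = 3.05e-06), including HLA-B, from 7.75 to 26.7 CPM, and the transactivator NLRC5. Of 18 blood cell markers 5 were tested, and all 5 rose, led by CORO1A (camera adjusted p = 0.000452). Of 25 epithelial markers likewise only 13 were tested. The filter keeps genes low in wild-type that are higher in another group, so rises of such markers are partly built in. TGF-beta target genes rose in 13 of 19 (camera adjusted p = 0.0021). These 8 calls held with an estimated correlation between genes. Adjusted over the list alone, the counts of members that rose were 24, 9, 28, 13, 5 and 13 for the 6 lists that rose, and 20 and 38 members fell in the 2 that fell. Over all genes tested, 9, 1, 3, 1, 0 and 3 members of the lists that rose fell, and no member of the other 2 rose.

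A further 6 list calls of clone 1 rested on the preset correlation. G2 and M phase genes fell in 41 of 54 (camera adjusted p = 0.00115; adjusted p = 0.304 with an estimated correlation), HMMR from 55.8 to 36.8 CPM. MYC target genes fell in 18 of 23 (adjusted p = 0.239 with an estimated correlation), NPM1 from 1704 to 905.9 CPM. Genes repressed by the EWSR1-FLI1 fusion of Ewing sarcoma were called up (adjusted p = 0.0751 with an estimated correlation): COL1A1 rose from 27.4 to 109.6 CPM and TNC from 19.3 to 67.3, but IGFBP5 fell from 15.4 to 0.191. Notch pathway genes (adjusted p = 0.0751 with an estimated correlation), with HEY1 at 39.7 CPM against 12.5, myogenic genes (adjusted p = 0.0677) and axon guidance genes (adjusted p = 0.345) were also called up by camera. When adjusted over the list alone, 41 G2 and M phase and 18 MYC target genes fell, and 15 genes repressed by the fusion, 14 Notch pathway, 8 myogenic and 24 axon guidance genes rose, the same numbers as over all genes tested. Members that went the other way numbered 5, 1, 4, 4, 1 and 13 over all genes tested.

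In total 5265 genes were higher and 5248 lower in clone 1 than in wild-type, 61.5% of those tested. With a change of at least 2-fold required as well, 1641 were higher and 693 lower. For each of the 7 counts of called genes given here, the direction with more genes turned under at least 1 alternative, so no excess of 1 direction is read from counts without a fold requirement.

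In clone 2 against wild-type GABRA5, a GABA-A receptor subunit, rose from 2.59 ± 0.452 to 129.7 ± 2.12 CPM, a log2 fold change of 5.65 (SE 0.070). DLK1, a Notch-like ligand from an imprinted locus, rose from 0.474 ± 0.136 to 16.8 ± 0.575 CPM. RAB3C, a GTPase of secretory vesicles, rose to 6.37 ± 0.669 CPM, TMTC1 to 4.54 ± 0.283 CPM, and CAVIN3 was at least 11.3-fold higher. TACR3, the neurokinin B receptor, went from 4.53 ± 0.397 CPM to no read and was at least 106-fold lower. PDGFRA, a receptor tyrosine kinase of mesenchymal cells, went from 8.84 ± 0.227 CPM to 3 reads, a ratio of 0.00485 with a counting interval of 0.000998 to 0.0143. SLC7A3 kept 2 reads and the histone gene H2AJ 1 read, and MCTP2 was at least 20.5-fold lower.

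Cell cycle genes led the groups that fell in clone 2. Of 54 G2 and M phase genes 49 fell (camera, Benjamini-Hochberg adjusted p = 2.6e-16), KIF23 from 117 to 58.8 CPM and CCNB2 from 111.8 to 60.9 CPM. Of 42 S phase genes 34 fell (camera adjusted p = 8.88e-13), RRM1 from 314.9 to 172.8 CPM, and of 23 cholesterol synthesis genes 20 fell (camera adjusted p = 2.92e-09), DHCR7 from 288.1 to 144.5 CPM. Antigen presentation genes rose in 13 of 15 (camera adjusted p = 1.76e-07), HLA-B to 34.6 CPM. Collagen and extracellular matrix genes rose in 22 of 36 and fell in 8 (camera adjusted p = 1.44e-05): VCAN rose from 0.114 to 2.22 CPM, while LUM went from 3.77 CPM to 2 reads and MMP2 fell from 1.95 to 0.178 CPM. Neuronal genes rose in 15 of the 22 tested, of 41 in the list (camera adjusted p = 0.000343), among them CACNA1A, CHGB and TUBB3. Here too the filter partly builds in rises of genes that are low in wild-type. FGF and receptor tyrosine kinase feedback genes rose in 16 of 25 (camera adjusted p = 0.00402), DUSP6 from 29.8 to 94.9 CPM and SPRY4 from 3.62 to 10.5 CPM. With an estimated correlation each of these 7 lists had an adjusted p of 0.0419. Adjusted over the list alone, 49, 35 and 20 members fell in the first 3 lists and 13, 22, 15 and 16 rose in the other 4. Over all genes tested, 1, 1 and 0 members of the first 3 rose and 1, 8, 4 and 4 of the others fell.

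Calls of 3 more lists in clone 2 were lost with an estimated correlation. Mitochondrially encoded genes rose in 14 of 15 (camera adjusted p = 1.69e-08; adjusted p = 0.263 with an estimated correlation), the rRNA MT-RNR2 from 1857 to 3997 CPM. Histone genes that depend on replication, measured here only as polyadenylated RNA, rose in 9 of 14 (adjusted p = 0.167 with an estimated correlation), H2BC5 from 25.7 to 60.5 CPM. Cytosolic ribosomal protein genes fell in 33 of 66 and rose in 11 (adjusted p = 0.603 with an estimated correlation), with RPL5 up from 1724 to 3701 CPM and RPS3 down from 2067 to 1003 CPM. When adjusted over the list alone, 15 mitochondrially encoded and 9 histone genes rose and 33 ribosomal protein genes fell.

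In total 5380 genes were higher and 5230 lower in clone 2 than in wild-type, and 1775 and 491 with a change of at least 2-fold. With upper quartile scaling 6413 were higher and 4257 lower, and without a filter 5323 and 5761. Genes of chromosome 11 were lower as a whole: the median log2 fold change of its 711 genes at 1 CPM or more was -0.60, and 88.9% of them were lower, against 50% of the genes of all other chromosomes. The same median was -0.02 in clone 1. CAVIN3, THY1, NCAM1, NLRX1, ANO5, RRM1, DHCR7 and RPS3, named here, lie on chromosome 11, and TYMS, NDC80 and TCF4 on chromosome 18. Genes of chromosome 18 had a median of -0.36 in both clones, and those of chromosome 13 had -0.29 in clone 1 and 0.10 in clone 2.

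**Figure D2:**
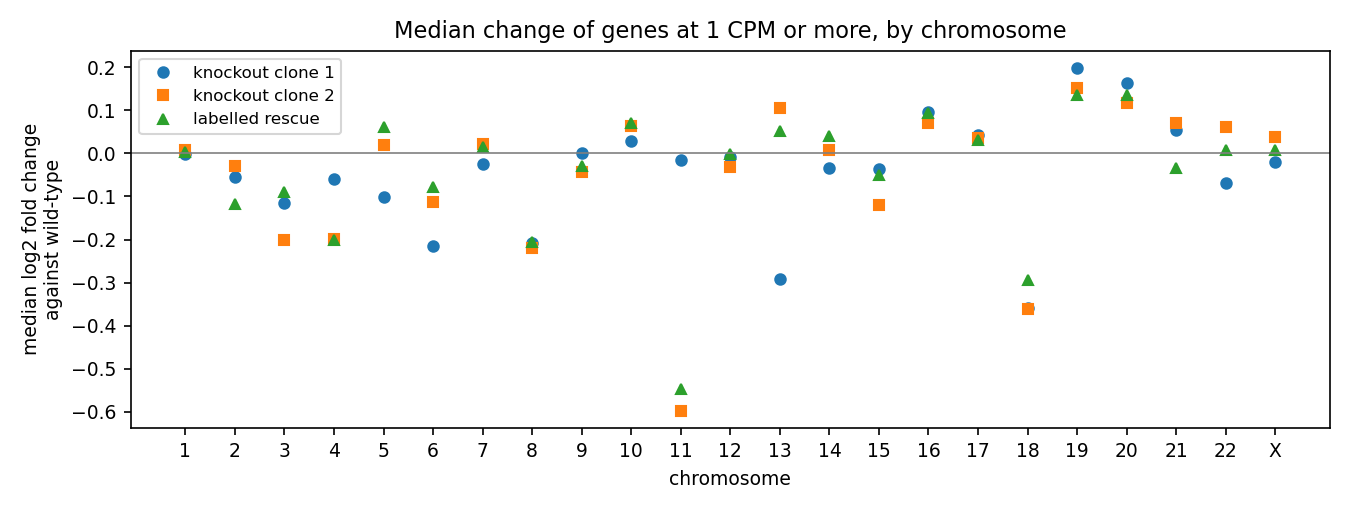
Median log2 fold change against wild-type of genes with at least 1 CPM, for each of chromosomes 1 to 22 and X, in clone 1 (circles), clone 2 (squares) and the libraries labelled rescue (triangles). Chromosome 11 stands at -0.60 in clone 2 and -0.55 in the libraries labelled rescue, against -0.02 in clone 1.

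The clones shared 5831 genes called in the same direction, 2816 higher and 3015 lower, or 3210 higher and 2475 lower with upper quartile scaling. Among those that rose in both, DLK1 stood at 8.35 ± 0.563 CPM in clone 1 and 16.8 ± 0.575 in clone 2, NEU4, a sialidase, at 5.81 ± 1.24 and 13.8 ± 1.3 against 0.507 ± 0.236 in wild-type, and RGS18, a regulator of G protein signalling, at 4.0 ± 0.0897 and 7.25 ± 0.177 against 0.301 ± 0.0981. FABP7, a fatty acid binding protein of radial glia, rose 96.7-fold and 20.6-fold. CACNA1A, a calcium channel subunit, rose 18.4-fold and 9.68-fold, and NRG2, a neuregulin, 21.3-fold and 11-fold. LHFPL7, ZDHHC11, C1orf127, PARP10 and ADGRE1 rose between 8.41-fold and 14.4-fold in each clone. ZDHHC11 has a close copy, so its value is uncertain.

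Among the genes that fell in both, SERPINF1, a secreted inhibitor of angiogenesis, went from 30.5 ± 0.75 CPM to 5.25 ± 0.285 in clone 1 and 2.15 ± 0.517 in clone 2. PDGFRA kept 6 and 3 reads and NUP210 2 reads in each clone. VANGL2, a planar cell polarity protein, fell to 0.0230 and 0.0209 of wild-type, and PIWIL2, of the piRNA pathway, to 0.108 and 0.0449. COL4A5, a basement membrane collagen, fell to 0.248 and 0.0111, and PMEPA1, a TGF-beta target, to 0.0324 and 0.207. LMX1A, ZNF43, PHETA2, KHDRBS3 and RAI14 fell to between 0.0470 and 0.233 of wild-type. Of the fixed lists, 38 G2 and M phase genes, 31 S phase genes and 18 cholesterol synthesis genes fell in both clones, and 16 collagen and extracellular matrix genes and 12 antigen presentation genes rose in both.

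With at least 2-fold required in each clone, 773 genes rose in both and 134 fell in both. Without that requirement, the clones shared 2816 higher and 3015 lower genes. Independent lists of the sizes called without it would share 1658 higher and 1607 lower genes, and simulated unchanged groups shared 0. Across the 17084 genes, which are not independent replicates, the fold changes of the clones had r = 0.387 against a simulated mean of 0.483 from the shared wild-type libraries alone, and a covariance of 0.356 against 0.0176, a difference of 0.338. With the same-numbered libraries of the clones correlated as well, the simulated means were 0.564 and 0.0206, and the shared genes still 0. The 3 wild-type libraries were too few to split, so part of the excess over independent lists may come from sharing them. Genes of some whole chromosomes also moved alike in both clones. Those of chromosome 18 had a median of -0.36 in each. Medians in clone 1 and clone 2 were -0.21 and -0.22 for chromosome 8 and 0.20 and 0.15 for chromosome 19. Those of chromosome 13 moved in opposite directions. Without chromosomes 11, 13 and 18 the shared genes numbered 5287. Chromosomes 8 and 19 stayed in, so this count is not free of shifts of whole chromosomes. What the shared calls owe to loss of ID2 and what to other differences of cloned lines from wild-type was not tested. A further 1726 genes were called in both clones in opposite directions.

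Between clone 2 and the libraries labelled rescue, APOD, an apolipoprotein, fell from 69.3 ± 4.38 to 4.21 ± 0.534 CPM, and THY1, a mesenchymal surface marker on chromosome 11, from 18.7 ± 5.32 to 1.24 ± 0.418 CPM. SDK2, an adhesion molecule of neurons, fell from 2.97 ± 0.352 to 0.152 ± 0.102 CPM, FATE1 kept 1 read, and VANGL2, at 7 reads in clone 2, was at least 2.64-fold lower. COL11A1, a fibrillar collagen, rose to 3.99 ± 0.673 CPM from 1 read, and ZPLD1 to 4.81 ± 0.206 CPM from 3 reads; neither was above 4 reads in wild-type or clone 1. FABP7 rose from 1.21 ± 0.288 to 7.21 ± 0.572 CPM and SCEL from 0.446 ± 0.149 to 3.16 ± 0.294 CPM. LUM rose from 2 to 18 reads, a ratio of 7.96 with a counting interval of 1.90 to 70.7, and lost its call without clone 2 replicate 1, with a log2 fold change of 2.12.

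Cell cycle genes were higher in the libraries labelled rescue. Of 54 G2 and M phase genes 51 rose (camera, Benjamini-Hochberg adjusted p = 9.21e-31), NDC80 from 46.2 to 67.3 CPM and KIF23 from 58.8 to 84.5 CPM. Of 42 S phase genes 35 rose (camera adjusted p = 1.06e-13), RRM2 from 472.8 to 676 CPM. Histone genes of the replication-dependent kind fell in 10 of 14 (camera adjusted p = 9.07e-08), H2AC6 from 127.3 to 53.7 CPM. Collagen and extracellular matrix genes fell in 22 of 36 and rose in 6 (camera adjusted p = 2.19e-16), COL6A3 from 13.6 to 2.42 CPM. Epithelial cell markers fell in 6 of 13 (camera adjusted p = 1.6e-07), CLDN4 from 9.06 to 0.973 CPM and KRT8 from 16.5 to 3.98 CPM. FGF feedback genes fell in 9 of 25 and rose in 7 (camera adjusted p = 0.000144), the falls led by SPRY4, ETV5, DUSP6 and EGR1. Adjusted over the list alone, 51, 36, 0, 7, 1 and 8 members of these 6 lists rose and 1, 1, 10, 26, 6 and 9 fell.

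Genes repressed by EWSR1-FLI1 were called down (camera adjusted p = 4.25e-06), COL1A1 from 65.1 to 12.4 CPM, and so were genes activated by it (camera adjusted p = 1.33e-05), NR0B1 from 213.6 to 116.4 CPM. Neural crest, Notch pathway, mesenchymal marker, TGF-beta target, IGF pathway and blood marker lists were also called down, at adjusted p between 0.00032 and 0.00768, with NGFR at 29.3 CPM against 73.8, JAG2 at 3.99 against 14.1 and PDGFRB at 24.7 against 66.3. Interferon-stimulated genes were called up (camera adjusted p = 0.0268; adjusted p = 0.0658 with an estimated correlation), 14 of 37 having risen. The other 14 calls held with an estimated correlation. With p-values adjusted over the list alone, 8 genes repressed by the fusion, 21 activated by it, 12 neural crest, 11 Notch pathway, 10 mesenchymal, 6 TGF-beta, 8 IGF pathway and 4 blood marker genes fell and 16 interferon-stimulated genes rose. Over all genes tested, the first 8 of these counts were 8, 19, 12, 10, 10, 6, 8 and 3, while 5, 6, 4, 2, 7, 4, 3 and 0 members of the same lists rose and 3 interferon-stimulated genes fell, so most of these lists went both ways.

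**Figure D3:**
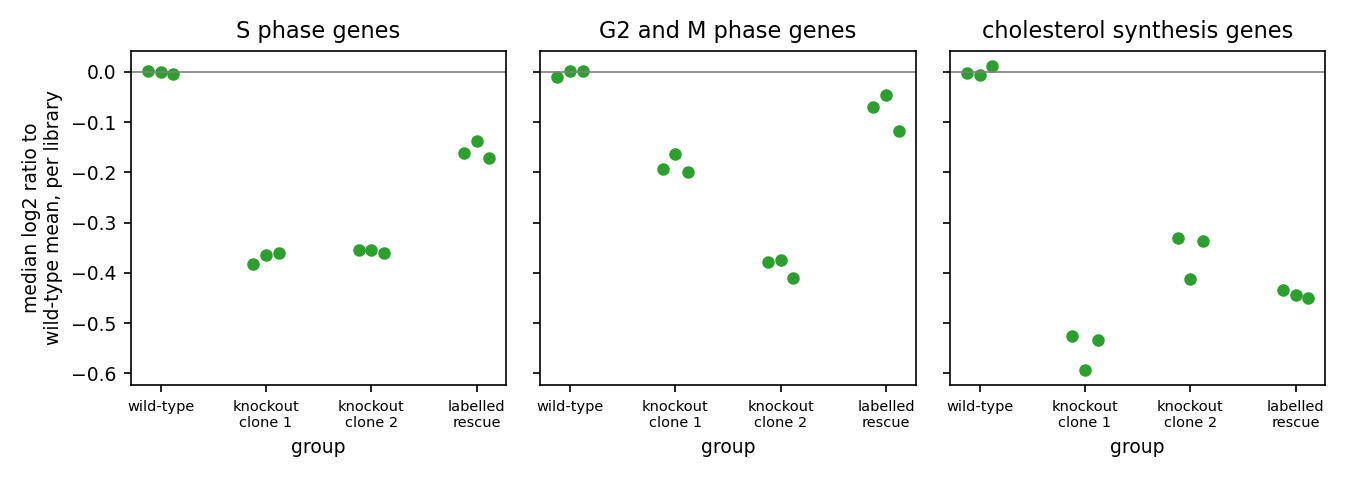
Median log2 ratio to the wild-type mean over the genes of 3 lists, for each of the 12 libraries, by group. Points are libraries. The G2 and M phase medians lie between -0.41 and -0.37 in clone 2 and between -0.12 and -0.04 in the libraries labelled rescue, and the cholesterol synthesis medians stay between -0.45 and -0.43 there.

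In total 3304 genes were higher and 3397 lower in the libraries labelled rescue than in clone 2, and 82 and 764 with at least 2-fold. With upper quartile scaling 2776 were higher and 3871 lower, but without a filter 3904 were higher and 3089 lower, and without rescue replicate 1 it was 3179 and 2882. Their direction cannot be read as that of more ID2 RNA, since ID2 itself was lower there.

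Of the 5831 genes called alike in both clones, 2354 moved back in the libraries labelled rescue, 1162 that had risen in the knockouts and 1192 that had fallen. With upper quartile scaling the split was 1338 and 904, and without a filter 1008 and 1477. CLDN4, a tight junction claudin, went from 1.04 ± 0.42 CPM in wild-type to 19.4 ± 2.72 and 9.06 ± 3.43 in the clones and back to 0.973 ± 0.142. CAMK1G, a calmodulin-dependent kinase, went from 0.313 ± 0.0564 to 2.31 ± 0.317 and 3.22 ± 0.143 and back to 0.302 ± 0.0564 CPM. LHFPL7, DNALI1, ARAP3, CACNA1A, KCNK13 and RAB37 followed the same course, and each fell to between 0.0789 and 0.190 of its clone 2 level. MBD3L4 and MBD3L5 did too, but their family is nearly identical in sequence and their counts are uncertain. In the other direction PRPH, the neuronal intermediate filament peripherin, went from 18.9 ± 1.34 CPM to 7.48 ± 0.838 and 4.38 ± 0.351 and then 12.2 ± 1.41, and STC1, a secreted glycoprotein, from 4.54 ± 0.133 to 1.43 ± 0.281 and 2.33 ± 0.376 and then 4.90 ± 0.245. JDP2, ANO5, FGFBP3, C16orf74, SYNE3, LHX9, INPP5J and EEPD1 rose between 1.60-fold and 1.90-fold over clone 2.

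By list, 36 of the 38 G2 and M phase genes and 27 of the 31 S phase genes that had fallen in both clones moved back, as did 13 of 16 collagen and extracellular matrix genes that had risen. Of 18 cholesterol synthesis genes that had fallen 3 moved back, and of 12 antigen presentation genes that had risen 5; differences between these shares were not tested. Of the 773 genes at least 2-fold higher in both clones 417 moved back, and of the 134 lower ones 17. A further 628 of the shared genes moved further from wild-type and 2849 were not called. Clone 2 enters both sides of this count, which favours opposite signs: for clone 2 against wild-type and rescue against clone 2 the covariance was -0.160 against -0.0192 simulated, a difference of -0.141, but the correlation was weaker than simulated, with r = -0.338 against -0.527 and Spearman -0.403 against -0.462. Counting called genes alone, 2004 rose and then fell and 1896 fell and then rose, where independent lists would share 1070 and 1011. Clone 1 shares no library with that comparison. Of the 10513 genes called in clone 1, 60.4% had the opposite sign in the libraries labelled rescue against clone 2, against 57.3% of all genes tested, and the fold changes correlated at r = -0.215 (Spearman -0.208) across genes.

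Against wild-type, the libraries labelled rescue had 4868 higher and 5114 lower genes, and 1159 and 679 with at least 2-fold. With upper quartile scaling 5537 were higher and 4470 lower, which turned the direction of the excess. GABRA5 stayed at 127 ± 1.94 CPM. FABP7 stood at 7.21 ± 0.572 CPM against 0.0571 ± 0.0329, and ZPLD1, COL11A1 and CAVIN3, with no wild-type read, were at least 119-fold, 98.3-fold and 19.9-fold higher. SLC7A3, COL4A5, VANGL2, TACR3 and NLRX1 had no read in the 3 libraries and were at least 157-fold, 148-fold, 132-fold, 120-fold and 75.7-fold lower. Cholesterol synthesis genes were lower in 16 of 23 (camera, Benjamini-Hochberg adjusted p = 6.19e-11; adjusted p = 0.0421 with an estimated correlation), MSMO1 at 54.1 CPM against 121.6. Antigen presentation genes were higher in 14 of 15 (adjusted p = 0.0631 with an estimated correlation), HLA-C at 48.9 CPM against 18.7. The ID and E protein list was lower (camera adjusted p = 0.0018, or 0.0633 with an estimated correlation), 5 of 7 members having fallen, ID3 to 82.0 CPM from 189.7. The targeted gene ID2 is itself among those that fell, with a log2 fold change of -0.91, so it adds to this call. S phase genes were still lower in 26 of 42 (adjusted p = 0.53 with an estimated correlation). Neuronal genes were higher (adjusted p = 0.0986 with an estimated correlation), as were interferon-stimulated (adjusted p = 0.143) and mitochondrially encoded genes (adjusted p = 0.53). Ribosomal protein genes (adjusted p = 0.743) and mesenchymal markers (adjusted p = 0.154) were called down, THY1 to 1.24 CPM against 28.5, though 12 of 66 and 8 of 20 members were higher. Adjusted over the list alone, 17 cholesterol synthesis, 26 S phase, 5 ID and E protein, 33 ribosomal protein and 11 mesenchymal genes were lower, and 14 antigen presentation, 12 neuronal, 22 interferon-stimulated and 13 mitochondrially encoded genes higher. Over all genes tested the neuronal count was 12, the interferon-stimulated 21, the mitochondrially encoded 13, the ribosomal 33 and the mesenchymal 11. Against the direction of their list went 2 cholesterol synthesis, 8 S phase, 1 ID and E protein, 1 antigen presentation, 5 neuronal and 7 interferon-stimulated genes. The list of mesenchymal markers lost its call without rescue replicate 2, with an adjusted p of 0.1 by camera. The median of chromosome 11 genes was -0.55, and of the 2354 genes that moved back 908 were no longer called against wild-type.

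The clones themselves differed in 10628 genes, 5174 higher and 5454 lower in clone 2, and 1245 and 1134 with at least 2-fold. With upper quartile scaling 6096 were higher and 4689 lower. GABRA5 stood at 129.7 CPM against 2 reads in clone 1, a ratio of 4708 with a counting interval of 1303 to 38880. NCAM1, a neural adhesion molecule on chromosome 11, stood at 33.5 ± 1.18 CPM against 0.202 ± 0.0853, and SLC7A2 at 19.9 ± 1.23 CPM against 3 reads. GPR27 and RAB3C, with no clone 1 read, were at least 212-fold and 154-fold higher. Of genes on the X chromosome, MAGEA12 kept 2 reads in clone 2 against 47.0 ± 1.35 CPM and CSAG1 1 read against 15.9 ± 0.271 CPM, though reads can be shared within the MAGEA family. GABRA3, TACR3 and MCTP2 had no clone 2 read and were at least 156-fold, 104-fold and 98.0-fold lower. Interferon-stimulated genes were lower in clone 2 in 24 of 37 (camera, Benjamini-Hochberg adjusted p = 7.13e-05; adjusted p = 0.0264 with an estimated correlation), BST2 at 0.277 CPM against 5.78, and epithelial markers in 8 of 13 (camera adjusted p = 0.000129; adjusted p = 0.0264 with an estimated correlation), EPCAM at 1.82 CPM against 18.7. The remaining 9 calls of camera were lost with an estimated correlation, with the adjusted p given for each: neuronal genes (adjusted p = 0.0741), FGF feedback genes (0.0588), mitochondrially encoded genes (0.49), genes activated by EWSR1-FLI1 (0.32) and cholesterol synthesis genes (0.316) were higher in clone 2, and G2 and M phase genes (0.32), collagen and extracellular matrix genes (0.0741), ribosomal protein genes (0.602) and blood cell markers (0.0927) lower. With p-values adjusted over the list alone, 24 interferon-stimulated, 8 epithelial, 39 G2 and M phase, 23 collagen and extracellular matrix, 42 ribosomal protein and 3 blood marker genes were lower in clone 2, and 12 neuronal, 15 FGF feedback, 13 mitochondrially encoded, 19 EWSR1-FLI1 activated and 12 cholesterol synthesis genes higher, the same numbers as over all genes tested. Over all genes, 6, 3, 6, 8, 8 and 2 members of the lists that were lower went up, and 9, 5, 0, 10 and 4 of the lists that were higher went down.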

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

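The test of chromosome 11 against GC content, length and level, and the regroupings of libraries, were fixed before their results were seen; the tests on loss of ID2, copies of chromosome 11, the excess of 2-fold rises and the rescue labels were chosen after the result was seen.

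The clones differed from each other under the same contrast with wild-type. ID2 was higher in clone 2 than in clone 1 by a log2 fold change of 1.49, and 1726 genes were called in opposite directions in the clones and also called between them. Lists that differed between the clones by camera with Benjamini-Hochberg adjustment were interferon-stimulated genes (adjusted p = 7.13e-05), epithelial markers (adjusted p = 0.000129), neuronal genes (0.000577), G2 and M phase genes (0.000626), collagen and extracellular matrix genes (0.00077), ribosomal proteins (0.00161), mitochondrially encoded genes (0.00161), FGF feedback genes (0.00239), blood cell markers (0.00492), genes activated by EWSR1-FLI1 (0.00917) and cholesterol synthesis genes (0.0136). Of these only the first 2 held with an estimated correlation.

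Of the 42 genes named for both clones or for a return in the rescue libraries, 29 were called between the clones by the edgeR quasi-likelihood test. Among genes that rose in both clones, the log2 fold change of clone 2 against clone 1 was -3.36 for CAVIN3, -2.23 for FABP7, -0.95 for NRG2, -0.93 for CACNA1A, -0.58 for C1orf127 and -0.56 for ADGRE1, and 1.02 for DLK1, 1.23 for NEU4 and 0.85 for RGS18. Among genes that rose and then moved back it was -4.63 for ARAP3, -2.22 for RAB37, -1.13 for DNALI1, -1.11 for CLDN4, -0.46 for MBD3L4, -0.38 for MBD3L5 and 0.46 for CAMK1G. Among genes that fell in both it was -4.48 for COL4A5, -1.48 for ZNF43, -1.44 for LMX1A, -1.27 for PIWIL2, -1.26 for SERPINF1, -0.89 for KHDRBS3, 0.72 for PHETA2, 2.31 for RAI14 and 2.67 for PMEPA1. Among genes that fell and then moved back it was -0.75 for PRPH, 0.74 for STC1, 0.76 for JDP2 and 0.77 for SYNE3.

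Genes of chromosome 11 were lower in clone 2 and in the libraries labelled rescue. A bias of GC content, gene length or level as the whole cause is argued against by regression on them, which left the median of the 711 genes at -0.599, from -0.60 before, with quartiles of -0.823 and -0.379. Loss of ID2 is argued against by clone 1, which had less ID2 RNA and a chromosome 11 median of -0.016. Fewer copies of chromosome 11 in the clone 2 line remain a candidate explanation: 100% of its 14 windows of 10 Mb had a median under -0.3, from -0.907 to -0.336. No copy number was measured here, so this stays a hypothesis.

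ID2 RNA was not higher in the libraries labelled rescue than in clone 2, with a log2 fold change of -0.288. A swap of the clone 2 and rescue labels was examined by the fold changes of clone 1 against wild-type and of labelled rescue against labelled clone 2. With a swap these should run together across genes, but they had a Spearman correlation of -0.2083. That holds only if rescue reverses the knockout and clone 1 shares its effects, which is itself in question. A swap is therefore not excluded, and ID2 RNA, at -0.288, lies in the direction that a swap would give. A construct whose transcript is not counted in the gene could give the same value, and no table here separates its reads from those of the gene, so this stays open. Whether ID2 protein returned was not analysed here.

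More genes were 2-fold higher than 2-fold lower in both clones. Noise of genes at low counts is argued against as the whole cause by genes with a mean of 4 CPM or more, of which 396 were higher and 192 lower in clone 2, 67.3% higher. The excess also differed with level, in classes of the mean over all groups, which share this limit. In clone 2 it was 267 against 89 at 4 to 16 CPM, and smaller at 16 to 64, with 100 against 81, and above 64, with 29 against 22. In clone 1 it was 271 against 139, 154 against 74 and 38 against 27, so among these classes the share of rises was lowest above 64 CPM. Below them, the excess in clone 1 was 420 against 130 under 0.5 CPM and 198 against 107 at 2 to 4 CPM, so it differed there too. What ties it to level was not tested. The excess did not depend on the choice among the scalings tried: the lowest share with the other scalings was 78.3% in clone 2 and 70.1% in clone 1. They moved the median log2 fold change of clone 2 only from 0.0134 to 0.0127 and 0.0825. A scaling error common to all of them was therefore not tested. An even background of DNA reads is argued against for genes at 4 CPM or more in clone 2, while clone 1 was not tested in this way. Of the 2208 genes under 0.5 CPM in wild-type 2.04% gained 2 CPM or more in clone 2. Their median gain there was 0.0803 CPM per kb, against 1.85 for the genes 2-fold higher at 4 CPM or more. The latter were chosen for their rise, so only the small gain of the former bears on a background. Reads from DNA at lower levels, or from unspliced RNA, stay open. Of those 2208 genes 81.2% were higher in clone 2, but this decides nothing, since the expression filter reads all groups and keeps genes with low wild-type levels that are higher elsewhere. Antisense genes had 178 2-fold rises and 12 falls in clone 2 and lincRNA genes 168 and 25. Under 4 CPM, however, their median log2 fold changes of 0.44 and 0.45 were close to the 0.46 of protein coding genes, with 0.20 for sense intronic genes and -0.05 for processed pseudogenes, so gene type does not settle it.

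Other groupings of the same libraries were tried. Genes called alike in both clones numbered 5831 for the real groups, the largest of 100 groupings (1 of 100). The highest other had 4188 and still had 7 of 9 libraries beside their group mates. Groupings that mix the lines widen the spread within groups. The rank thus shows that the lines differ, and it does not exclude chance agreement between clones that share the wild-type libraries. The genes that moved back numbered 2354, against 4 for the highest other grouping (1 of 100). That count needs calls in several comparisons at once, and the median over regroupings was 0 genes called in clone 1. Its rank therefore does not exclude chance opposite signs between comparisons that share knockout libraries. The list calls numbered 59 against 58 for the highest other grouping (1 of 100). The margin was 1 call in a draw of 99 groupings, and the median grouping gave 29, so this rank does not exclude chance. Groups that mix the lines thus get many list calls too. No regrouping was run with an estimated correlation. Chance was not excluded for the share of clone 1 calls with the opposite sign. There 60.37% was reached by 5 of 100 groupings, the real one included, and the highest other was 100% of 7 called genes. For the 5 comparisons of 3 against 3 libraries the 10 groupings are too few for a share under 0.05: the real counts were 10513, 10610, 6701, 9982 and 10628, each 1 of 10, and the highest other was 0 in each, groupings of the clones that part the same-numbered libraries included.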

How the results depend on the processing

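The alternative without chromosomes 11, 13 and 18 was chosen after seeing the data; the others were planned. Counts of calls stayed within 1.5 times their main value except for the list calls, of which 32 of 59 held with an estimated correlation, and with a log2 fold change of at least 1 required, where fewer genes pass by construction: 2334 in clone 1, 2266 in clone 2, 846 for rescue against clone 2, 1838 for rescue against wild-type, 2379 between the clones, 907 in both clones, 282 moved back (279 that had risen and 3 that had fallen), and a share of opposite signs of 66.54%. The last value pools 76.17% of the genes that rose and 43.72% of those that fell in clone 1, against 57.32% of all genes tested. The share was 59.41% with upper quartile scaling and 61.59% without a filter; the cause was not tested. Leaving out 1 library gave 9776 to 10211, 9806 to 10216, 5785 to 6175, 9186 to 9661 and 9933 to 10187 calls for the 5 comparisons, 5257 to 5698 in both clones, 2033 to 2313 moved back, a share of 59.18% to 61.29%, and 58 to 61 list calls. No named gene or list call changed sign, but for each of the 7 counts of genes the direction with more genes turned under 3 to 6 alternatives. Of single genes 21 calls were lost, all but 1 by the 2-fold requirement, among them ID2 in clone 2 (-0.62); the other was LUM in rescue against clone 2. Of the 59 list calls 27 were lost under at least 1 alternative, all 27 with the estimated correlation. Against wild-type, the rescue lists of S phase (0.0534), neuronal (0.0635), mesenchymal (0.0842) and ribosomal genes (0.0534) lost theirs by camera without chromosomes 11, 13 and 18, as did interferon-stimulated genes against clone 2 (0.0567); the mesenchymal list also did with the stricter filter (0.058) and without rescue replicate 2 (0.1). With replicate number as a block the counts were 10577, 10668, 6783, 10004, 10689, 5880 and 2415, the share 60.15% and the list calls 62, and none of 212 named gene and list calls changed. Over all groups 6 of 18 same-numbered pairs had r over 0.1, from -0.136 to 0.245, and 6 of 12 libraries were closest to their own number; 3 of those 6 pairs join the clones, whose comparison had 10689 calls with the block and 10628 without. In the simulations of the 5 comparisons 40% to 62% of the genes with the smallest simulated change were recovered; depth was not varied. Few reads limit single folds, as the counting interval of 1.90 to 70.7 for LUM in rescue against clone 2 shows.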

Other observations

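The X chromosome, imprinted and protocadherin genes named here and the neighbour pattern were chosen after the result was seen; the shuffling test of neighbours was then fixed before its own result was seen.

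Several MAGEA genes on the X chromosome were higher in clone 1 than in wild-type. MAGEA3 stood at 84.8 ± 0.256 CPM (SD, n = 3) in clone 1 against 1.68 ± 0.344 in wild-type, 0.204 ± 0.0426 in clone 2 and 0.165 ± 0.0475 in the libraries labelled rescue, and MAGEA6 at 45.5 ± 1.51 CPM against 0.891 ± 0.0352 in wild-type. MAGEA1 stood at 5.53 ± 0.941 CPM against 2.08 ± 0.649, and MAGEA4 at 1.54 ± 0.504 CPM against 1 read in wild-type. CTAG2 had 130 reads in clone 1, 1 in wild-type and 0 in the other groups. Reads can be shared between members of the MAGEA family. GABRA3, a GABA-A receptor subunit from the same part of the X chromosome, stood at 6.68 ± 0.397 CPM in clone 1 and 0.134 ± 0.0367 in wild-type.

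H19, an imprinted RNA of chromosome 11, stood at 6.82 ± 0.641 CPM in clone 1 and 0.231 ± 0.16 in wild-type, while its neighbour IGF2 was at 0.628 ± 0.128 and 0.894 ± 0.143 CPM and was not called in clone 1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.165). On chromosome 14, DLK1 and its neighbour MEG3 were both higher in both clones, MEG3 at 5.64 ± 1.31 CPM in clone 1 and 2.56 ± 0.0874 in clone 2 against 1.02 ± 0.31 in wild-type. Of the protocadherin genes of chromosome 5, PCDHB15 was at 2.53 ± 0.159 CPM in clone 1 and 0.314 ± 0.0335 in wild-type, and PCDHGC3 at 82.2 ± 1.04 and 85.3 ± 4.58 CPM.

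Genes next to each other changed together more often than in shuffled gene orders. Of 10712 adjacent pairs, 69 were both at least 4-fold changed in 1 direction in clone 1, against a mean of 21.6 and a highest value of 47 over 10000 shuffles, and 50 of the 69 pairs rose. In clone 2 there were 28 pairs against a mean of 9.4 and a highest value of 24, and 22 rose. Pairs of genes that overlap or whose symbols begin alike were not counted, so neighbours of a gene family with such symbols were left out. Shared reads of near-identical neighbours with unlike symbols could still add pairs and were not separated here. Switching of chromosome segments in single clones may underlie part of the genes that differ between them. A shuffle of gene order cannot tell it from other causes of joint change in neighbours.

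Of the 37 lists 13 were called by camera in none of the 5 comparisons, with smallest Benjamini-Hochberg adjusted p between 0.0638 for endothelial markers and 0.678 for WNT pathway genes. They also held HOX cluster genes (0.15), p53 target genes (0.118), hypoxia response genes (0.152) and tissue-restricted bHLH factors (0.597).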
